A study of Danio rerio with 12 samples.

How the data were processed

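Gene expression was measured in whole zebrafish embryos on 6 Agilent arrays with 2 colours each, which gave 12 samples in 4 groups of 3. Per the labels, M embryos lacked the maternal contribution of the gene pou5f3 (spg), MZ embryos lacked both the maternal and the zygotic one, and each sample pooled 60 to 100 embryos. Every array carried an M and an MZ sample of 1 stage and 1 replicate number, in opposite dyes. At sphere, MZ was labelled with Cy3 on 2 of 3 arrays, and at 40% epiboly it was labelled with Cy5 on 2 of 3 arrays. Both deposited files of an array were identical, so each sample was read from the channel of its labelled dye.

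The intensity values of the scanner files were made with Agilent Feature Extraction 9.5.3.1, per the file headers, and the annotation on the arrays used the Zv4 build (danRer2). The mean spot intensity and the local background intensity were used as deposited. The Feature Extraction processed intensity, which per the file headers is background-subtracted, spatially detrended and dye-normalised, served as an alternative. The authors also deposited a table of intensity values on a linear scale. Per the series' design text, channels were split and quantile normalised for it, and experiments were run in biological triplicate. Each column of that table followed the processed intensity of its own sample and dye (Spearman correlation across probes from 0.9952 to 0.9985, at most 0.9824 with any other sample). The column medians lay between 555.2 and 555.7. The target distribution and the treatment of dim spots in that table are not given in the sources used here.

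Background was corrected with normexp at an offset of 50. The offset shrinks fold changes of dim probes towards 0. Channels were split and quantile normalised together over the 12 samples. The 1417 control spots were left out after background correction, and spots with an outlier flag in either channel were left out on that array. The 2 spots of each of the 21495 probes were averaged on the log2 scale. A probe was tested if it lay well above background in all 3 samples of at least 1 group, with at least 0.5 of its kept spots, which left 13318 probes. The probe with the highest mean stood for its gene, so 11172 genes were tested. Symbols were updated through RefSeq accessions of the GRCz12tu table for 7342 probes, and 504 further probes took the symbol of another probe of the same name. Other probes kept the name in the file. Of the tested genes, 4932 had a gene symbol.

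Differences between MZ and M were fitted with limma 3.58.1 in R 4.3.3, with the array as a block and the dye as a covariate, over all 12 samples. The fit had 3 residual and 2.34 prior degrees of freedom. The contrasts were the genotype difference at each stage, their mean, and the difference between the stages. The stage differences within M and within MZ lie between arrays, so the array was a random block there, with a consensus correlation of 0.705. All p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All sphere arrays lay on slide 1 and in scan 1, and all epiboly arrays on slide 2 and in scan 2, so stage and slide cannot be told apart. The genotype comparisons at each stage lie within arrays, but their difference between the stages lies between slides.

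The pairing by shared array was checked on the deviations of samples from their group means. The 2 samples of an array correlated at 0.53 to 0.88 across genes on all 6 arrays, and no sample exceeded -0.01 with a sample of another array of its stage. Deviations from a group mean sum to 0, which pushes the correlations between arrays below 0, so these add little to the check. The 12 samples had between 12363 and 14615 probes above background, and at most 3 saturated spots. The number of arrays limits the precision. The median SD between replicates was 0.09 at sphere and 0.13 at 40% epiboly, on the log2 scale.

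The genes named were set by a rule written before the data were examined. For each contrast the rule took the 12 largest rises and 12 largest falls (8 for stage differences) with an adjusted p under the threshold, a gene symbol, and a value and the same sign on every array. For the difference between stages, the ratios per array of the stages were not to overlap, and for the stage differences the groups were not to overlap, so a gene without a value on an array of the contrast was left out. The rule also took the mutated gene and, for each of 14 gene lists, the 4 members with the smallest p. Some genes that the rule took are not reported here. The lists were fixed at the same time, and their members were matched by current symbol and then by the older names on the array. The pattern for ribosomal proteins also caught 2 S6 kinase genes, which were left out. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance and compares them with no other genes.

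The fits were tested on simulated data of 11061 genes with 200 changed genes. At sphere, 88% of genes changed 1.5-fold and 92% of genes changed 2-fold were recovered, and 5.94% of calls were false. For the difference between stages, 62% of genes changed 1.5-fold at 1 stage and 86% of genes changed 2-fold were recovered, and 4.97% of calls were false. For the stage difference in M, 60% of genes changed 1.5-fold and 80% of genes changed 2-fold were recovered, and 8.2% of calls were false. Normal noise was drawn on normalised values, so normalisation was not tested. The stage simulation held no slide effect. Far fewer genes were changed than were called in the data, so these shares need not hold there. In the simulated list test at sphere, 10 of 10 shifted lists and 0 of 10 unshifted lists were called. The simulated genes varied independently, whereas the estimated correlation was 0.371 in the measured Nodal-responsive list. The simulation therefore does not test the preset correlation. Alternatives were fits without the array block or the dye, other background corrections, normalisations and filters, every probe, the authors' table, and leaving out each array. The fit with loess took loess within arrays together with Aquantile normalisation between arrays, in place of quantile normalisation of the channels, and these steps were not tried apart. Counts of changes of at least 2-fold were added after seeing the data.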

Results

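Zebrafish embryos with the m793 allele of pou5f3 (spiel ohne grenzen), a POU-family transcription factor, were compared at sphere (4 hours after fertilization) and at 40% epiboly (5 hours). MZ embryos lacked the maternal and the zygotic contribution, and M embryos lacked the maternal one only. The comparison addressed which transcripts differ when the zygotic contribution is lost as well. Each of the 4 groups held 3 samples of 60 to 100 embryos. Values are normalised log2 intensities, and differences are MZ minus M unless stated otherwise. Standard errors came from fits over all 6 arrays, of which 3 carried each stage. Largest refers to genes with a symbol that passed the test with a value and the same sign on every array of the comparison. Between 55.9% and 65.8% of spots per sample lay well above background.

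The mutated gene itself was measured first. The transcript of pou5f3 was lower in MZ by a log2 fold change of -0.74 ± 0.03 at sphere (SE, n = 3 arrays per stage, adjusted p = 0.000158) and -0.57 ± 0.03 at 40% epiboly (adjusted p = 0.000291). In this fit, which corrects for dye, MZ embryos thus held 59.7% and 67.2% of the M level. The group means, not corrected for dye, were 14.15 in MZ and 14.82 in M at sphere. At 40% epiboly they were 14.46 and 15.11, a similar gap. The probe lies on chromosome 16 from 27995572 to 27995631 in Zv4, and its place in the transcript is not annotated in the files. A second probe of pou5f3, from 27995532 to 27995591, gave -0.73 and -0.45. The transcript stayed well above background in all samples, so it is no test of the protein, and the labels do not say which part of the gene the allele alters. The difference between the stages did not pass (0.17, adjusted p = 0.0557, with loess 0.25, without the array block 0.947 and without the dye term 0.978). Without the array block the calls at sphere and at 40% epiboly ended (adjusted p = 0.0874 and 0.175, the highest of their alternatives, with 0.00041 and 0.00132 the lowest).

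**Figure D1:**
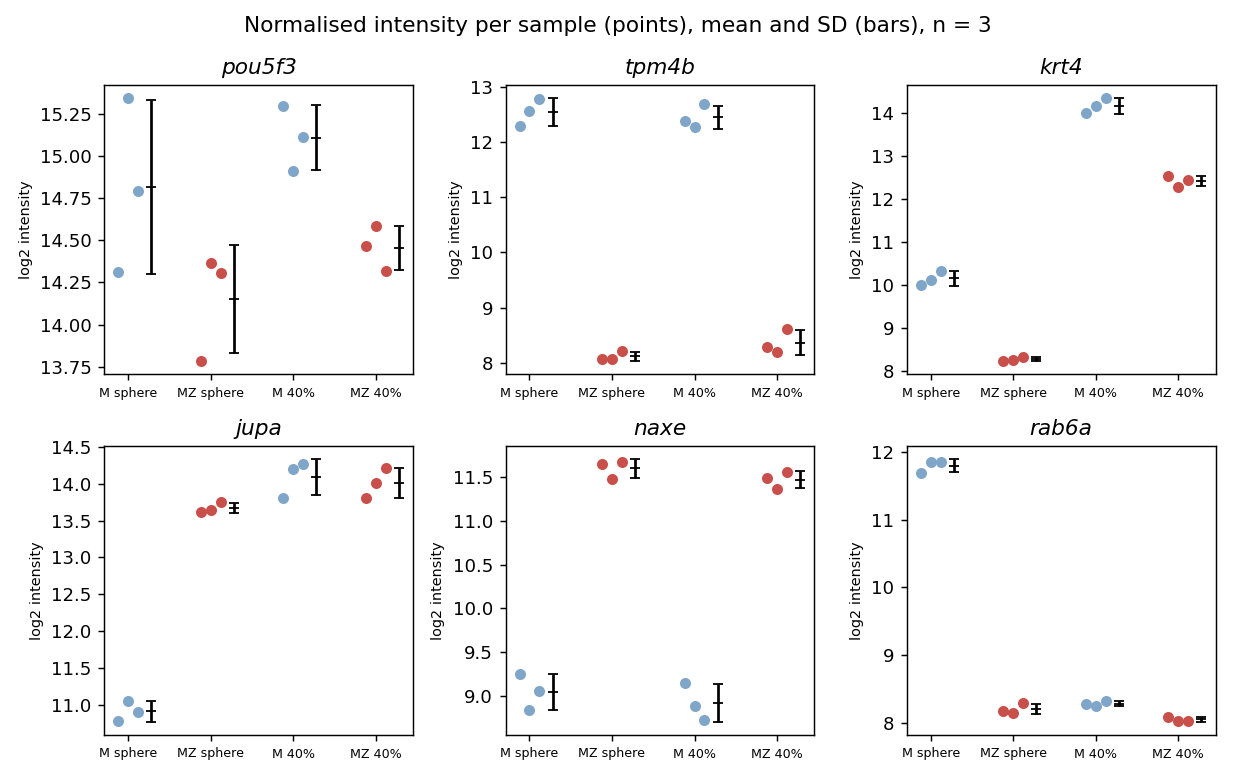
Normalised log2 intensity of 6 genes in each sample, with points for samples and bars for the mean and SD of 3 samples per group, where 40% stands for 40% epiboly. The genes other than pou5f3 were picked for display after their values were seen. The axes differ between panels, and tpm4b had a mean of 12.54 in M and 8.12 in MZ at sphere.

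At sphere, the largest changes were losses in MZ. The tropomyosin gene tpm4b was 21.5-fold lower (log2 fold change -4.43 ± 0.07, adjusted p = 1.79e-05), rab6a, a small GTPase of the Golgi, was 12.3-fold lower, and apoeb, an apolipoprotein gene of the yolk syncytial layer, was 7.14-fold lower. The other largest falls were in plcd1b, lfng, cyp2v1, gas6, mxtx2, nr4a1, fezf2, marcksl1a and ved, with log2 fold changes from -2.72 to -2.38. The largest rise was in jupa, which encodes plakoglobin, a protein of cell junctions (2.75 ± 0.07, adjusted p = 5.64e-05, probe on chromosome 11 from 7714271 to 7714330 in Zv4). It was followed by naxe, nedd8, mif4gda, orc3, rx2, sri, cwc27, f9a, hax1, pard3ab and gatm, with log2 fold changes from 2.57 to 1.45. The eye field gene rx2 was not well above background in any M sample, and its group mean after loess was at least 3-fold higher in MZ. For this bound, each M sample was set to its floor, the lowest value of any of its probes above background after loess, where it lay below that floor. The bound is not corrected for dye. The loess fit with the dye term gave rx2 a log2 fold change of 1.509, which is below 3-fold and did not pass (adjusted p = 0.121). For sri and pard3ab the other probe of the gene had the opposite sign. The other probe of naxe, which overlapped the first, gave a smaller rise (1.268 against 2.572). Probes that did not overlap the first gave smaller falls for cyp2v1 (-0.555), gas6 (-1.86) and apoeb (8 probes, from -0.612 to -2.492, against -2.836 for the first).

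Many genes of dorsal, mesendodermal and signalling lists fell at sphere. The lists were not independent, since 22 of 298 genes were in more than 1 list. The Nodal-responsive and dorsal organizer lists shared foxa2, foxa3, gsc, ndr1 and ndr2, and all 5 fell. Of 21 measured Nodal-responsive mesendoderm genes, 16 fell, 1 rose and 4 did not pass, with examples in lft2, a Nodal inhibitor (-1.44 ± 0.06), cxcr4a, a chemokine receptor (-1.87 ± 0.08), and foxa3 (-1.80 ± 0.06). Of 16 dorsal organizer genes, 11 fell and 1 rose, among them nog1, a BMP antagonist (-1.34), dkk1b, a Wnt inhibitor (-1.41), and gsc (-1.86). Of 13 Fgf pathway genes, 9 fell and 1 rose, including the ligand fgf17 (-1.59), the receptor fgfr4 (-1.94) and the phosphatase dusp6 (-1.63). There were 16, 11 and 10 falls and 1 rise in each when adjusted over the list alone. The list test (camera) gave adjusted p = 1.19e-08, 1.06e-06 and 6.94e-05 for the lists in this order, and adjusted p = 0.181 for each with an estimated correlation.

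Other lists of regulators also held genes that fell at sphere. Of 14 pluripotency-related and SoxB factors 11 fell and 0 rose, where pou5f3 itself is a member and 1 of the falls, with sox19a at -1.71, klf2a at -1.44 and sox11a at -1.26 (12 falls adjusted over the list alone). Of 15 ventral and BMP genes 6 fell and 3 rose, and the transcriptional repressor ved (-2.38), gata2a (-1.89), bambia (-1.29) and vox (-0.90) fell (7 falls and 3 rises adjusted over the list alone). Of 20 Wnt and posterior mesoderm genes 12 fell and 2 rose, with sp5a at -1.71 and wnt11 at -0.88 (12 and 2 adjusted over the list alone). The list tests gave adjusted p = 1.65e-05, 0.00306 and 0.000117, and adjusted p = 0.181 for each with an estimated correlation. Of 32 neural and regional patterning factors 13 fell and 9 rose, both overall and adjusted over the list alone, and camera did not pass (adjusted p = 0.0554, from 0.0138 to 0.467 over the alternatives, with a pass at 0.0138 without the array block, 0.0409 without the dye term and 0.0325 with fry). The forebrain factor fezf2 fell (-2.47), as did zic2b (-1.86) and gbx1 (-1.48), and six3a rose (0.97).

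Some markers of the layers around the blastoderm differed between the genotypes at sphere. Of 13 yolk syncytial layer genes 8 fell and 1 rose, in the list alone also 8 and 1 (adjusted over the list alone), with mxtx2 at -2.55 and gata5 at -1.31 (list test adjusted p = 0.00042, and adjusted p = 0.195 with an estimated correlation). Of 19 enveloping layer and epidermis genes 8 fell and 3 rose, with the same counts adjusted over the list alone. The keratins krt18a.1 (-1.88), krt4 (-1.85) and krt8 (-1.10) fell, krt5 did not pass (0.11, adjusted p = 0.205), and cki and cyt1 were near background in both genotypes. The largest rise was in tacstd (1.24), which was chosen after its values were seen and is in the adhesion list too. The list median was 0 and the mean -0.43 (list test adjusted p = 0.0423, from 0.00028 to 0.181 over the alternatives, with loess 0.0716, and adjusted p = 0.181 with an estimated correlation).

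Stress, cell cycle, adhesion, maternal and ribosomal genes were counted at sphere as well. Of 22 p53, apoptosis and stress genes 11 fell and 2 rose (11 and 3 adjusted over the list alone), with hspb1, a small heat shock protein, at -1.79 and gadd45ba at -1.52 (list test adjusted p = 0.00324, and adjusted p = 0.341 with an estimated correlation). Of 26 cell cycle genes 9 fell and 3 rose (11 and 3 adjusted over the list alone), with mcm3, a replicative helicase subunit, at -1.69 and rrm2l at 0.70 (list test adjusted p = 0.0454, from 0.0136 to 0.195 over the alternatives, without the array block 0.0574, and adjusted p = 0.195 with an estimated correlation). Of 25 adhesion, migration and matrix genes 10 fell and 5 rose (11 and 5 adjusted over the list alone), with rhoab at -1.01 and has2 at -0.79 (list test adjusted p = 0.0466, from 0.00132 to 0.181 over the alternatives, with loess 0.0768, without the array block 0.151, and adjusted p = 0.181 with an estimated correlation). Of 20 maternal oocyte and germ line transcripts 9 rose and 3 fell (9 and 4 adjusted over the list alone), with the germ cell helicase ddx4 at 0.73 and figla at -0.91 and with pou5f3 again among the falls, and camera did not pass (adjusted p = 0.224, from 0.00297 with fry to 0.341 over the alternatives). Of 64 ribosomal protein genes 15 fell and 7 rose, in the list alone as well (adjusted over the list alone), and the list test did not pass (adjusted p = 0.123, from 0.11 to 0.7 over the alternatives).

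In all, 4012 of 11172 genes passed at sphere in limma, 2235 higher and 1777 lower in MZ. Of these, 67 were at least 2-fold higher and 219 at least 2-fold lower. Without the array block 1491 genes passed, with loess 2005, and 2530, 2085 and 2086 on leaving out sphere array 1, 2 and 3 in turn, and with processed intensities, which carry no offset, 1294 at 2-fold or more. Of the genes named above, klf2a, bambia, vox, ddx4 and rhoab did not pass without the array block, and rx2, pard3ab, gata5 and has2 did not pass with loess.

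**Figure D2:**
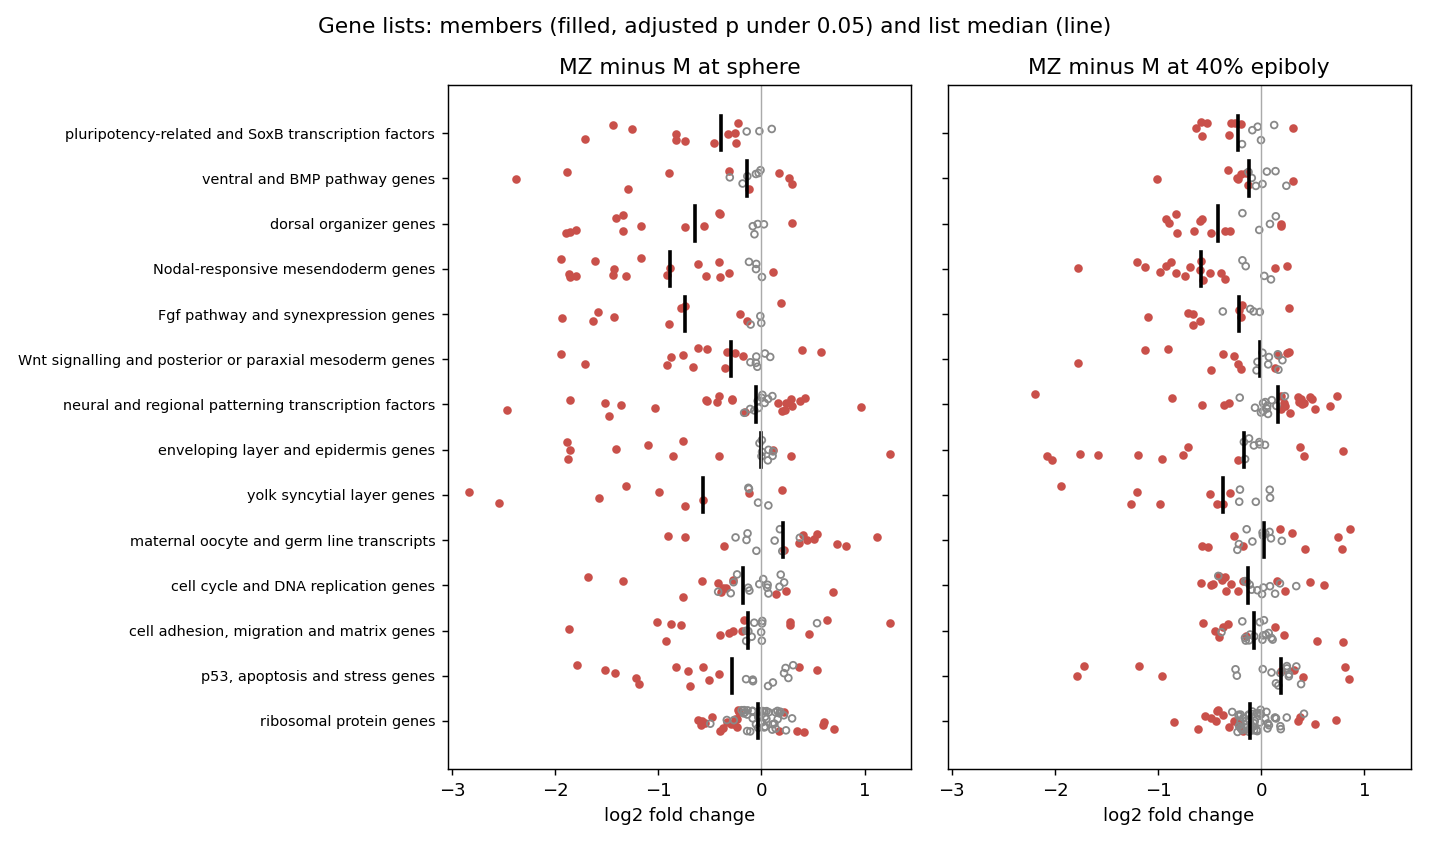
MZ minus M in log2 fold change (horizontal axes) for the members of 14 gene lists (rows) at sphere and at 40% epiboly. Filled points passed at an adjusted p under 0.05, open points did not, and the line is the list median, which for Nodal-responsive genes was -0.89 at sphere and -0.59 at 40% epiboly.

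At 40% epiboly, the largest fall was again in tpm4b (-4.07 ± 0.07, adjusted p = 3.27e-05). It was followed by ctsll, plcd1b, anxa1a, fezf2, slc35h1, trappc11, p4ha1b, krt5, krt8, sesn3 and dcaf13, with log2 fold changes from -2.80 to -2.01. Among the largest rises was ankhb, which was 6.91-fold higher in MZ (2.79 ± 0.08, adjusted p = 5.25e-05, probe on chromosome 2 from 33264279 to 33264338 in Zv4). Others among the largest rises were in lpcat4, dbr1, naxe, rgs14a, faima, itih2, gpr137c, gpc1b, rx2 and orc3, with log2 fold changes from 2.80 to 1.93. The gene rx2 again was not well above background in any M sample. Its group mean after loess, not corrected for dye, was at least 3.96-fold higher in MZ. For rgs14a the other probe of the gene had the opposite sign (-0.08). For ankhb 1 of 2 other probes did (-0.02), and the other one (2.81) overlapped the first. The overlapping probe of naxe gave 1.26 against 2.533 for the first. Probes that did not overlap the first gave 0.27 for gpr137c, -1.06 for slc35h1, -1.45 for krt8, and -0.29 and -2.09 for krt5.

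Many mesendodermal genes were lower in MZ at 40% epiboly as well. Of 21 Nodal-responsive genes 15 fell and 2 rose (16 and 3 adjusted over the list alone), with the T-box factor tbx16 at -1.77 ± 0.04 and gata6 at -1.21 ± 0.08. Of 16 dorsal organizer genes 10 fell and 2 rose (11 and 2 adjusted over the list alone), with foxa3 at -0.92 and nog1 at -0.82. Of 13 Fgf pathway genes 8 fell and 1 rose (10 and 1 adjusted over the list alone), with the feedback inhibitor spry4 at -1.10 and fgf8a at -0.71. Of 13 yolk syncytial layer genes 8 fell and 0 rose, with the same counts adjusted over the list alone, and apoeb was at -1.95 and hnf1ba at -1.26. The list tests gave adjusted p = 6e-05, 0.00232, 0.000783 and 0.000783, and adjusted p = 0.35 for each with an estimated correlation.

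Keratins led the enveloping layer list at 40% epiboly. Of 19 measured members 9 fell and 3 rose, with the same counts adjusted over the list alone, and krt5 (-2.08 ± 0.06), krt8 (-2.03 ± 0.07), cki (-1.59) and cyt1 (-1.20) fell (list test adjusted p = 0.00322, and adjusted p = 0.35 with an estimated correlation). Of 14 pluripotency-related and SoxB factors 8 fell and 1 rose, in the list alone too (adjusted over the list alone), with klf17 at -0.58 and sox19a at -0.63 (list test adjusted p = 0.00322, and adjusted p = 0.35 with an estimated correlation). Of 32 neural and regional patterning factors 15 rose and 5 fell (18 and 5 adjusted over the list alone), with pou3f3a at 0.66 and pax6b at 0.48 higher and fezf2 at -2.19 lower. Their median was 0.17 (list test adjusted p = 0.0142, from 0.0119 to 0.48 over the alternatives, with loess 0.0813, and adjusted p = 0.48 with an estimated correlation). Of 64 ribosomal protein genes 13 fell and 4 rose (10 and 3 adjusted over the list alone), with rpl36 at -0.84 (list test adjusted p = 0.0181, from 0.00847 to 0.629 over the alternatives, without the array block 0.0913, with fry 0.216, and adjusted p = 0.629 with an estimated correlation).

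Camera at the preset correlation did not pass for the other groups at 40% epiboly. Over the alternatives, the adjusted p ran from 0.00626 to 0.35 for the ventral list, from 0.00525 to 0.607 for the Wnt list and from 0.0129 to 0.795 for the maternal list. The lowest of each came from fry, and the ventral list also passed without the dye term (0.0475). The stress, cell cycle and adhesion lists passed in none of the alternatives run. Of 15 ventral and BMP genes 7 fell and 1 rose (8 and 1 adjusted over the list alone, adjusted p = 0.0515), with vox at -1.01. Of 20 Wnt and posterior mesoderm genes 8 fell and 4 rose (8 and 5 adjusted over the list alone, adjusted p = 0.357), with msgn1 at -0.37 and tbxta at -1.13. Of 22 stress genes 4 fell and 5 rose, also adjusted over the list alone, with a median of 0.19, a mean of -0.05, camera upward and fry downward (adjusted p = 0.778). The members gadd45ba (-1.79), hspb1 (-1.18) and junba (-0.96) fell, and mdm4 (0.82) rose. Of 20 maternal transcripts 6 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.699), with ddx4 at 0.86. Of 26 cell cycle genes 10 fell and 4 rose (10 and 5 adjusted over the list alone, adjusted p = 0.198), and ccnb2 was at 0.61. Of 25 adhesion genes 6 fell and 4 rose (7 and 5 adjusted over the list alone, adjusted p = 0.543), and the E-cadherin gene cdh1 was at 0.80.

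In all, 4058 of 11171 genes passed at 40% epiboly in limma, 2211 higher and 1847 lower in MZ, of which 125 were at least 2-fold higher and 150 at least 2-fold lower. Without the array block 1683 genes passed, with loess 2380, with the epiboly arrays alone 2509, and 2272 on leaving out epiboly array 2, and with processed intensities 1194 at 2-fold or more. Of the genes named above, sox19a, mdm4, ddx4 and cdh1 did not pass without the array block, nog1, fgf8a, spry4, sox19a and msgn1 did not pass with loess, and sesn3 did not pass without epiboly array 2.

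**Figure D3:**
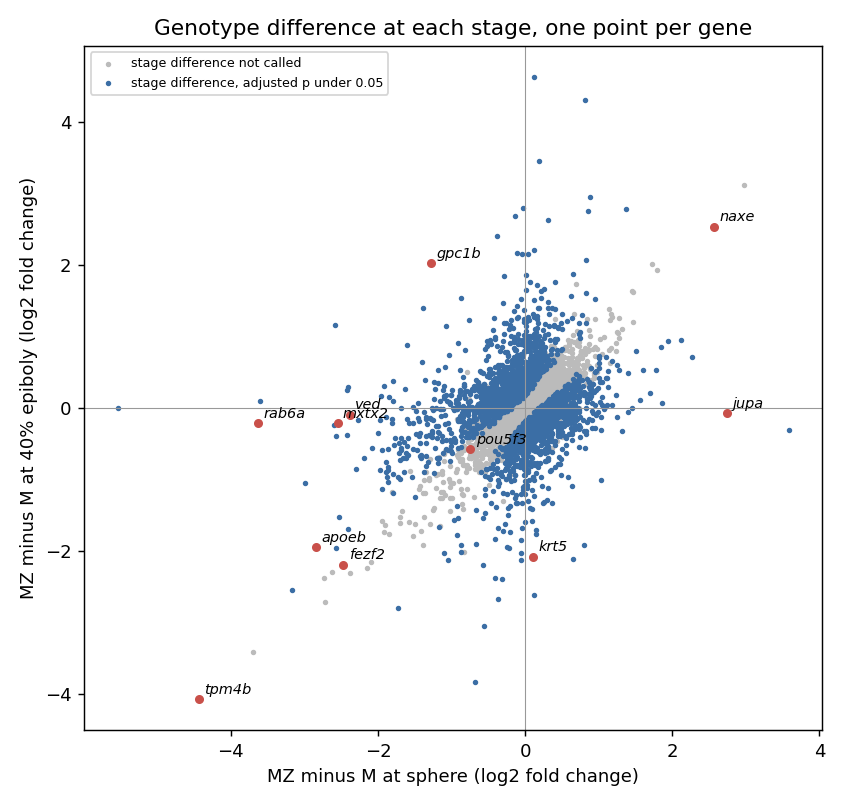
MZ minus M at sphere (horizontal axis) and at 40% epiboly (vertical axis), in log2 fold change, with 1 point per gene. Blue points passed the test of the difference between stages, and red points are labelled genes, such as rab6a at -3.62 and -0.21.

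Averaged over both stages, the largest falls were in tpm4b (-4.25 ± 0.05), plcd1b (-2.71), apoeb (-2.39) and fezf2 (-2.33), and among the largest rises were naxe (2.55 ± 0.07) and ankhb (2.08). The rule for naming required the same sign on all 6 arrays, which 3105 of the genes that passed had. In all 5309 genes passed in limma, 2937 higher and 2372 lower in MZ, against 2572 without the array block and 3343 with loess. At both stages 1000 genes were higher, where 442.4 are expected of independent lists, and 790 were lower, where 293.8 are expected. Another 164 genes were higher at sphere and lower at epiboly, and 228 the reverse. The stages shared no sample, but they shared the estimates of the dye effect and of the spread of each gene. The calls at the stages are thus not independent, and the expected counts are no exact baseline. The neural list had a median of 0.02 and a mean of -0.11 here, with camera downward and fry upward (adjusted p = 0.989).

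The genotype difference itself differed between the stages, and so between the slides, for many genes. A slide difference in the ratios cannot be told apart from stage here. The fit held 1 dye effect for both slides, and an effect for each slide was not tried for this difference. Among genes with a value on all 6 arrays whose ratios per array did not overlap between the stages, the largest gains from sphere to epiboly were in rab6a (difference of effects 3.41 ± 0.07, adjusted p = 7.34e-05) and gpc1b (3.30 ± 0.10, adjusted p = 0.000168), and gpc1b went from -1.28 to 2.02. The largest drops were in jupa (-2.82 ± 0.10) and p4ha1b (-2.75 ± 0.06). For rab6a and jupa the level changed mostly in M. The rab6a samples lay at 11.69 to 11.86 in M at sphere and at 8.03 to 8.32 in the other groups. The mean of jupa went from 10.91 to 14.09 in M and from 13.67 to 14.02 in MZ. The difference went from -2.38 to -0.09 for ved and from -1.63 to 0.27 for dusp6. The keratin krt5 went from 0.11 to -2.08. Of 16 dorsal organizer genes 9 gained and 1 dropped (11 and 1 adjusted over the list alone), and of 32 neural factors 13 gained and 2 dropped (15 and 2 adjusted over the list alone). Their list tests gave adjusted p = 0.00138 and 0.0034, and adjusted p = 0.577 for each with an estimated correlation. Of 21 Nodal-responsive genes 9 gained and 2 dropped (10 and 3 adjusted over the list alone), and of 22 stress genes 8 gained and 1 dropped, also adjusted over the list alone (list tests adjusted p = 0.0244 and 0.0364, from 0.0132 to 0.577 and from 0.021 to 0.577 over the alternatives, without the array block 0.0784 and 0.0704, with fry 0.0624 and 0.132, and adjusted p = 0.577 for each with an estimated correlation). The median, mean and test differed in sign for the ventral list (-0.02, 0.34, upward) and the enveloping layer list (0.06, -0.11, downward), which did not pass with camera (adjusted p = 0.237 and 0.871, from 0.00186 with fry to 0.577 and from 0.00141 with fry to 0.937 over the alternatives). In all 2553 genes passed in limma, 1305 up and 1248 down, against 708 without the array block and 878 with loess, of which 554 went up and 324 down. Without sphere array 1, 2 or 3 or epiboly array 2, 1573, 1227, 1303 and 1192 genes passed, and without the array block dusp6 did not pass (adjusted p = 0.0565).

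Between sphere and 40% epiboly, the keratins krt4 and krt8 rose in both genotypes. In M embryos the largest rises were in ctsll (4.30 ± 0.17), krt8 (4.18 ± 0.11), krt4 (4.02 ± 0.15) and krt5 (3.81 ± 0.11). The largest falls were in vangl2, a planar polarity gene (-4.88 ± 0.33), lpcat4 (-4.58 ± 0.51) and rab6a (-3.54 ± 0.07). In MZ embryos krt4 (4.12 ± 0.15), apoeb (3.92 ± 0.15), alcamb (3.54 ± 0.18) and stm (3.48 ± 0.20) rose most, fgf8a rose as well (3.35 ± 0.07), and vangl2 (-5.60 ± 0.33) and pgp (-1.90 ± 0.23) were among the largest falls. Of 21 Nodal-responsive genes 14 rose in M and 14 in MZ (14 and 16 adjusted over the list alone), and of 13 yolk syncytial layer genes 9 and 10 rose (9 and 11 adjusted over the list alone). Stage was fully shared with slide and scan, so a slide difference cannot be told apart from it. In limma 3636 genes passed in M (2125 higher, 1511 lower) and 2684 in MZ (1563 higher, 1121 lower), and 50 (36 higher, 14 lower) and 89 (81 higher, 8 lower) when each channel was only centred on its 75th percentile. Without sphere array 1, 2 or 3 or epiboly array 2, 1745, 1642, 1618 and 1646 genes passed in MZ.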

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

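The tests of shared samples and of the age of the embryos, and the 2-fold limit, were chosen only after related results had been seen. The genotype difference was not the same at the stages for 2553 genes in the limma test of the difference itself, where stage and slide cannot be told apart. No group held enough samples for a test of single outlying samples.

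Genes that lacked a value on any of the 6 arrays were left out here, among them cyp2v1, mxtx2, gbgt1l4 and thy1, whose differences passed and were larger than some or all of those given. Among the other genes with a symbol whose ratios per array did not overlap between the stages, the largest gains in MZ minus M from sphere to 40% epiboly, as differences of log2 effects, were 3.41 for rab6a, 3.304 for gpc1b, 2.827 for lpcat4, 2.822 for dbr1, 2.781 for tfap2e and 2.778 for rgs14a. Further gains were 2.486 for nr2f1a, 2.368 for lfng, 2.289 for ved, 2.213 for zmat2, 2.187 for itih2 and 2.129 for cnot4b. The largest drops were -2.82 for jupa, -2.754 for p4ha1b, -2.185 for krt5, -2.069 for anxa1a, -2.067 for trappc11 and -2.035 for ctsc. Further drops were -1.851 for ctsd, -1.792 for faah2a, -1.789 for nedd8, -1.74 for cxadr, -1.727 for impdh1a and -1.69 for utp4. Of these, zmat2, trappc11 and ctsd did not pass without the array block, and lpcat4, itih2 and faah2a did not pass with loess. Without epiboly array 2, lpcat4 (2.379), zmat2 (1.837), trappc11 (-1.74) and ctsc (-1.805) did not pass.

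At 40% epiboly MZ minus M ran against the change from sphere to epiboly in M. On arrays that shared no sample with that change, genes that rose at least 2-fold from sphere to epiboly in M had a median MZ minus M of -0.369 (567 genes), and genes that fell at least 2-fold had a median of 0.287 (359 genes). The correlation across genes, which are not independent replicates, was then -0.492, which argues against measurement noise of shared M samples as the source. The M level at epiboly still enters both differences with opposite signs, so expression particular to M there would give a negative correlation too. The M level at sphere enters both with the same sign, so the correlations of the stages are not directly comparable. Of 275 genes called at 2-fold or more at epiboly, 45 (16.4%) had an MZ mean over 1 log2 unit outside the range of the M means. For those genes this argues against a lower age of MZ embryos as the whole cause. It does so only if levels between the stages stay within that range, which was not measured. A variant under the probe could also place a gene outside. The other 230 lay within the range or at most 1 log2 unit outside it, 123 of them between the M means. An age difference as part of the cause may remain, since at sphere the rising genes had a median of -0.196 (445 genes), but the falling genes there had -0.001 and the correlation was -0.061, so the tables do not decide it, and an effect of the genotype on the pace of development stays open as well.

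At sphere or 40% epiboly 70 genes differed by at least 4-fold, among them tpm4b, which had no second probe that passed. A sequence variant under the probe could give this, and 50% of 20 other probes of 11 of these genes, none overlapping the first, had under 0.5 times the change, with a probe of slc35h1 that was tested at both stages counted at sphere. When it is counted at either stage the share is 55%, over the 50% set in advance for a variant, but 1 probe decides this, so a variant cannot be told apart from a change of the transcript. Probes of 1 gene are not independent, and 8 of the 20 were of apoeb, while for 6 of the 11 genes every such probe and for 3 none had under 0.5 times the change at either stage. Alleles linked to pou5f3 could differ too, and of 31 tested genes among the 200 nearest neighbours, 1 was called at 2-fold or more, with an odds ratio of 1.25 (95% interval 0.0304 to 7.64, Fisher's exact test, p = 0.56), which leaves this open, and different parents of the groups were not tested.

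Other splits of the samples were counted for each comparison. The mean over both stages called 5309 genes in the real split. Of the 30 splits by swaps within arrays that could be fitted, 1 called as many, the real one, a share under the 0.05 set in advance. The other splits still held the genotype difference, which adds to their spread and lowers their counts, so this share does not exclude chance. The highest of the other splits had 2553 genes and swaps the genotypes of 1 whole stage, which is the difference between stages. The splits were too few for a share under 0.05 in the other comparisons. The sphere and epiboly comparisons called 4012 and 4058 genes against at most 0 in the other of 10 splits. Some of these other splits put both samples of an array in the same group and so did not keep the pairing by array. The difference between stages and the stage differences in M and MZ called 2553, 3636 and 2684 genes against at most 0 in the other of 9 splits that could be fitted. In all these comparisons the other splits still held the real genotype, stage or slide differences. These add to the spread and lower the counts, so counts of 0 are no measure of chance.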

How the results depend on the processing

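The limit of 2-fold was added after the data were seen. With no replicate block the counts were 1491 at sphere, 1683 at epiboly, 2572 for their mean and 708 for the difference between stages, and with neither block nor dye term 1562, 1933, 2685 and 855. With loess and Aquantile, which replaced quantile normalisation together and are called loess here, they were 2005, 2380, 3343 and 878, and 63.1% of the last went up, against 51.1%. With the epiboly arrays alone 2509 genes passed at epiboly. Leaving out 1 array gave 2085 to 4354 genes at sphere (2530, 2085 and 2086 without sphere array 1, 2 and 3), 2272 to 3883 at epiboly (2272 without epiboly array 2), 1192 to 2786 for the difference between stages and 1618 to 2560 for the stage difference in MZ. In the last 2, sphere arrays 1, 2 and 3 and epiboly array 2 each moved the count, to 1573, 1227, 1303 and 1192, and to 1745, 1642, 1618 and 1646. With centring on the 75th percentile the stage differences fell to 50 genes in M (72% higher) and 89 in MZ (91% higher). Counts at 2-fold or more at sphere, at epiboly and for the difference between stages, the only ones run, stayed within 1.5 times under every other fit than those on processed intensities and on the authors' table. The first gave 1294 at sphere (36.5% higher, against 23.4%), 1194 at epiboly and 1395 for the difference, and the authors' table gave 1112 (35.1% higher), 1061 and 1251. The processed intensities carry no offset, and an offset by construction shrinks folds of dim probes, but its share in this change was not tested. The cause of the other changes was not tested either. The stage difference of the effect on tbx16 reversed from -0.855 to 1.625 with processed intensities (adjusted p = 0.00299), and did not pass with loess (-1.173, adjusted p = 0.261), and tbx16 was not well above background in any MZ sample at sphere. No other of 324 single-gene results reversed. Besides pou5f3, which lost its calls at sphere and at epiboly, 59 lost their call with no replicate block and 46 with loess, and 41 of the leave-one-out values did, as did 6 with processed intensities and 3 with no dye term. Of 56 list results, 4 lost their call with loess, 7 with no replicate block, 4 with fry and 1 with no dye term, and 34 lost their call with an estimated correlation and 0 held one. There were also gained list calls, 12 with fry, 2 with no dye term and 1 with no replicate block. Signal over background limits the dim probes.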
